A study of Homo sapiens with 33 samples.

How the data were processed

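Gene expression was measured in Karpas422, a human diffuse large B cell lymphoma cell line that the series title describes as EZH2 mutant. Cells were given EED226, an allosteric inhibitor of the Polycomb repressive complex PRC2 that binds its EED subunit, at 5 µM, or the solvent DMSO. The 33 arrays fell into 11 groups of 3, taken from the sample titles: 0 h, and DMSO or EED226 at 8 h and at the times that the series' design text gives as 1, 2, 3 and 6 days. The titles give these times in hours. The labels do not say how the cells at 0 h were treated. The design text calls the replicates biological triplicates, and states no shared batch or day. It speaks of an EZH2 inhibitor and the protocol text also names the compound EI1, while every treated sample's title names EED226; groups follow the titles, and no sample labelled with EI1 was analysed here.

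Total RNA was extracted with TRIZOL and labelled with a 3' IVT kit for Affymetrix arrays, per the labels' protocols. The deposited values are log2 expression values per probe set, 1 column per array, which the authors made with RMA, per the submitters' processing notes. RMA corrects background, normalizes arrays by quantiles and summarizes the probes of a probe set. Its version, and the arrays it was run on together, are not given in the sources used here. Array medians lay between 4.06 and 4.18 on the log2 scale. The upper parts of the deposited distributions differed: the 75th percentile was 6.10 on DMSO day 6 replicate 3 and 6.69, 6.73 and 6.67 on the EED226 day 6 arrays. For arrays, their number limits the precision. The 3' labelling makes values depend on RNA integrity, which was followed with the 3' and 5' control probe sets of ACTB and GAPDH.

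The table held 54675 probe sets, of which 62 were Affymetrix controls. In the platform annotation 41091 probe sets had 1 gene symbol, 1801 had several and 11777 were not named here; probe sets with several symbols or none were left out of gene results. Each of 19775 genes was represented by its brightest probe set by the mean over all arrays, and 10523 genes had more than 1 probe set. As these include the EED226 arrays, the choice may favour probe sets that rose with EED226. Counts of changes of at least 2-fold were not made with the mean of a gene's probe sets. Of 115 named genes, 75 had other probe sets in the comparison that named them, and for 25 of these at least 1 probe set had the opposite sign. Probe sets that can match several transcripts measured 45 of the named genes. No genome build was used for the values, so no coordinates are given. Gene order was taken from a RefSeq gene table of the human assembly GRCh38.p14, only to find neighbouring genes.

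Differences were tested with limma 3.58.1 in R 4.3.3 on the deposited log2 values, with lmFit and eBayes, 1 mean per group over all 33 arrays and 22 residual degrees of freedom. Tests were two-sided. Genes with a Benjamini-Hochberg adjusted p under 0.05 within a comparison are said to have passed the test, and no filter on dim genes was used. EED226 was compared with DMSO at each of 5 times, over all times with an F test, and between times as a difference of differences, day 6 minus day 1 and day 6 minus day 3. DMSO at each time was compared with 0 h; these comparisons share the 0 h arrays. For 33 gene lists fixed before the data were examined, as were the design, the alternatives and the rule for named genes, camera with a preset correlation of 0.01 tested whether the members moved against other genes, adjusted over the lists. Camera with an estimated correlation and fry were alternatives. Values with ± are SD over 3 arrays where levels are given, and log2 differences carry their limma SE.

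Among genes that passed the test and whose 3 values did not overlap those of the control, which chance gives for 10% of genes, the rule takes the 8 largest rises and 6 largest falls at day 6 and the 6 and 4 largest at other times. It adds the 2 members of each gene list with the smallest p at day 6, always EED, EZH2, EZH1 and SUZ12, and the 5 largest differences in each direction between times. For DMSO against 0 h it takes 6 rises and 6 falls at day 6 and 3 and 3 at other times. Genes named outside this rule are marked as chosen after their values were seen.

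The procedure was tested on simulated data for the day 6 comparison with 19775 genes, of which 200 were changed. It recovered 52.2% of changes of 0.5, 98.5% of changes of 1 and 100% of changes of 2 on the log2 scale, with 6 false calls. Of the 33 lists, 1 was shifted by 0.3 and was called, and 0 of the other 32 were. Genes were simulated independently of each other, so this could not show false list calls that come from correlated genes.

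Replicate numbers were checked for pairing by the correlation of same-numbered arrays' deviations from their group means. Every correlation between EED226 and DMSO exceeded 0.1 at 8 h (0.199 to 0.318), day 1 (0.110 to 0.358) and day 2 (0.151 to 0.169). The numbers of the titles may therefore pair the arrays at these times, which the labels do not state and no test decided. The lowest correlation was -0.00879 at day 3 and 0.0464 at day 6, and between DMSO and 0 h arrays the lowest was under 0.1 at every time. Alternatives were a replicate block, only genes above the median level, renewed quantile normalization, centring on array medians, the mean of a gene's probe sets, trended robust eBayes, array weights, only the 6 arrays compared, a 2-fold minimum, 0 h arrays as control, and leaving out each replicate. A covariate for the ACTB 3' to 5' difference, DMSO 8 h as control for the interferon list, camera on DMSO against 0 h, and a fit without DMSO day 6 replicate 3 were added after seeing the data. Other splits of the arrays were refitted, all 10 for each comparison of 3 with 3 arrays and 100 distinct ones, the real one included, for the any-time and between-time tests. Those 100 were drawn a second time after the shares of the first draw had been seen, because it had allowed a split to be repeated; both results are given. Figures were drawn with matplotlib 3.10.9.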

Results

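Expression was measured with 33 Affymetrix arrays of Karpas422 cells, in 11 groups of 3: cells at 0 h, and cells given DMSO or 5 µM EED226 for 8 h or for 1, 2, 3 or 6 days. Values are the deposited RMA values on the log2 scale. Arrays of a group correlated with r of 0.994 or more across probe sets, except DMSO day 6 replicate 3, with r of 0.987 and 0.986 to the other 2 arrays of its group. The number of genes that passed the test grew from 0 at 8 h to 172, 1866, 4536 and 10081 at days 1, 2, 3 and 6, and 8025 of 19775 genes passed the test over all times.

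**Figure D1:**
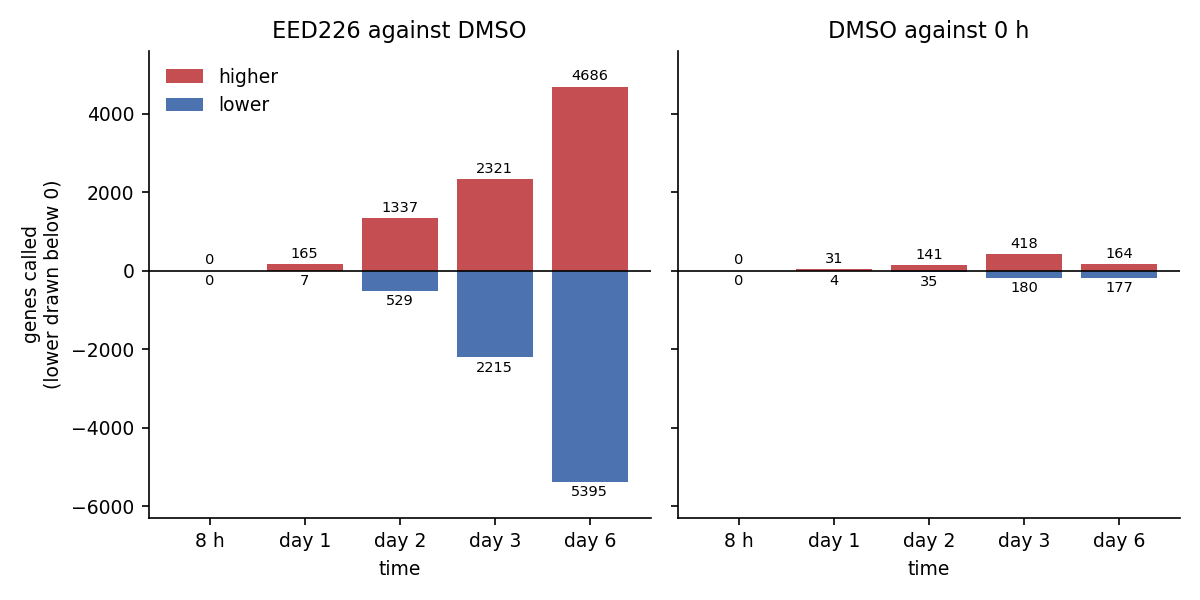
Genes that passed the limma test in each comparison, with the time on the x axis and the number of genes on the y axis; red bars count genes that were higher and blue bars, drawn below 0, genes that were lower. EED226 against DMSO goes from 0 genes at 8 h to 4686 higher and 5395 lower at day 6, and DMSO against 0 h has at most 418 higher, at day 3.

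The genes of PRC2 itself were followed first, as the complex that EED226 inhibits. EZH2, the catalytic subunit, differed from DMSO by 0.02 ± 0.08 log2 units (SE, n = 3) at day 1 and fell by 0.78 ± 0.08 at day 6, from 10.26 ± 0.02 to 9.48 ± 0.17 (SD, n = 3). SUZ12 fell by 0.42 ± 0.07 and EED, the subunit that binds the compound, fell by 0.27 ± 0.05 at day 6 (adjusted p = 6.68e-05). The mean of EED's probe sets gave a rise of 0.25 (adjusted p = 0.0467), and with only the 6 arrays compared the adjusted p of its fall was 0.0533. EZH1, the other catalytic subunit, was 0.85 ± 0.08 higher, with 2 of its 4 other probe sets of opposite sign. PHF19, an accessory subunit, fell by 1.94 ± 0.10, and JARID2, which helps recruit the complex, rose by 1.34 ± 0.10, with 1 of its 2 other probe sets of opposite sign. Of the 14 measured genes of PRC2 subunits and H3K27 demethylases, 5 were higher and 8 lower at day 6, and the list did not pass (camera adjusted p = 0.626).

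At 8 h no gene separated EED226 from DMSO. With limma, 0 of 19775 genes passed the test, and every alternative analysis of the genes that was run also gave 0. An unadjusted p under 0.05 was found for 401 genes, fewer than chance alone gives on average. This shortfall may come from a test that is cautious at this time, so it is no further evidence against an effect. TMEM100, KIAA1210 and RIN2, which rose later, had differences of 0.05 ± 0.17, -0.04 ± 0.18 and 0.17 ± 0.16 log2 units (SE, n = 3) at this time, with an adjusted p of 1.00 each. None of the 33 gene lists passed; 2 did with only genes above the median level, 2 without DMSO 8 h replicate 2 and 2 without EED226 8 h replicate 3.

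At day 1 the first genes rose. ECI2, an enoyl-CoA isomerase of fatty acid oxidation, was 1.58 ± 0.14 log2 units (SE, n = 3) higher with EED226, from 5.26 ± 0.14 to 6.84 ± 0.18 (SD). SERPINE2, a serine protease inhibitor, rose by 1.58 ± 0.25, TMEM100 by 1.52 ± 0.17, SLC25A43, a mitochondrial carrier with a dim DMSO mean of 3.68, by 1.44 ± 0.23 and ABAT, which degrades GABA, by 1.20 ± 0.23. KIAA1210 rose 2.83-fold, from 4.48 ± 0.23 to 5.98 ± 0.16 (SD). Falls were smaller: TRIM17, NMUR2, DELEC1 and MORN3 had differences of -0.60 ± 0.14, -0.55 ± 0.13, -0.48 ± 0.10 and -0.38 ± 0.09, with adjusted p of 0.0386, 0.0308, 0.0199 and 0.0352. TRIM17 (3.81 in DMSO, 3.21 with EED226) and DELEC1 (3.03 and 2.56) lay below the lowest array median of 4.06 in both groups, as SLC25A43 did in DMSO. Sizes are uncertain at such levels. In all, 165 genes rose and 7 fell (limma), 17 of the rises by at least 2-fold. The calls of these 4 falls did not hold in most fits without 1 array of day 1, which also have fewer arrays. In the fits that lost them the differences were -0.50 to -0.68 for TRIM17, -0.44 to -0.59 for NMUR2, -0.38 to -0.49 for DELEC1 and -0.29 to -0.42 for MORN3. TRIM17 lost its call without DMSO replicate 1 or 3 (adjusted p = 0.272 and 0.146) or EED226 replicate 1, 2 or 3 (0.223, 0.0637 and 0.134), and NMUR2 without DMSO replicate 1, 2 or 3 (0.12, 0.154 and 0.0717) or EED226 replicate 1 or 3 (0.125 and 0.19). DELEC1 lost it without DMSO replicate 1 or 2 (0.0662 and 0.142) or EED226 replicate 1 or 2 (0.118 and 0.18), and MORN3 without DMSO replicate 2 or 3 (0.295 and 0.0701), EED226 replicate 1, 2 or 3 (0.113, 0.232 and 0.0532) or with trended robust eBayes (0.117). ABAT lost its call without DMSO day 1 replicate 3 (1.03, adjusted p = 0.0712) and without EED226 day 1 replicate 2 (1.11, adjusted p = 0.0542), and with only the 6 arrays compared the 4 falls, of the same size, had adjusted p of 0.0956, 0.0939, 0.213 and 0.212.

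Interferon-response genes, which cells induce against viruses, led the gene lists at day 1 with a median of 0.30 over 36 genes. Of these, 1 passed over all genes, IFIT1 at 0.56, and 16 passed when adjusted over the list alone (camera adjusted p = 4.08e-18; adjusted p = 0.212 with an estimated correlation). Of 16 PRC1 subunits, the other Polycomb complex, PHC1 rose by 0.30 and RYBP, with 1 of 3 other probe sets of opposite sign, by 0.40 (list adjusted p = 0.0131; adjusted p = 0.726 with an estimated correlation). The lists for MHC class I (median 0.10, adjusted p = 0.0131), MHC class II (0.04, 0.0185) and, downwards, T and NK cell markers (-0.08, 0.0131) were called without any member passing. With an estimated correlation their adjusted p were 0.946, 0.946 and 0.686. Among 123 developmental transcription factors known as classical PRC2 targets, SOX9 rose by 0.83, MEIS1 by 0.74 and HOXC4, named after its value was seen, by 0.30; the list did not pass (adjusted p = 0.852). In the PRC2 list JARID2 rose by 0.41, with 1 of 2 other probe sets of opposite sign, and EPOP, also named after its value was seen, by 0.38; EPOP fell by 0.25 ± 0.09 at day 6. With the replicate number as a block, 296 genes passed, 282 higher and 14 lower. The count depended on single arrays: it was 93, 99 and 78 without DMSO day 1 replicate 1, 2 and 3 (6, 3 and 2 of them lower), 60 and 77 without EED226 day 1 replicate 1 and 2 (1 and 2 lower), and 284 in a fit without DMSO day 6 replicate 3 (14 lower), and 3 lists rather than 5 passed without DMSO day 1 replicate 2.

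At day 2 the interferon genes moved as a group. Of 36 measured genes 32 rose and none fell, with a median of 1.27 (camera adjusted p = 1.15e-60; adjusted p = 0.000472 with an estimated correlation). RSAD2, which encodes the antiviral protein viperin, rose from 7.28 ± 0.10 to 10.06 ± 0.22 (SD, n = 3), a difference of 2.78 ± 0.24 (SE), and IFIH1, a cytosolic sensor of double-stranded RNA, by 2.73 ± 0.17. RIN2 rose by 3.01 ± 0.16, though its 1 other probe set had the opposite sign at this time, TMEM100 by 2.92 ± 0.17, KIAA1210 by 2.72 ± 0.18 and HEPACAM2 by 2.67 ± 0.16; the DMSO means of IFIH1, RIN2 and HEPACAM2 (3.59, 3.79 and 3.25) lay below the lowest array median of 4.06, where sizes are uncertain. Lymphotoxin alpha (LTA) and TNF, neighbouring cytokine genes, fell by 1.66 ± 0.18 and by 1.33 ± 0.15. The transcription factor EGR1 fell by 1.08 ± 0.35, with an adjusted p of 0.0484, and NHSL1 fell by 1.00 ± 0.23. The call of EGR1 was lost without any of the 6 arrays of this day (adjusted p = 0.181, 0.0902 and 0.0812 without DMSO replicate 1, 2 and 3, and 0.0573, 0.0686 and 0.249 without EED226 replicate 1, 2 and 3), with trended robust eBayes (0.0675) and with the ACTB covariate (0.0562). Its difference was -0.82 to -1.21 without single arrays, -1.08 with trended eBayes and -1.04 with the covariate.

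Of 18 genes of MHC class I presentation 12 rose at day 2 (median 0.41, adjusted p = 7.18e-10), and of 16 MHC class II genes 5 rose (0.17, 0.00146). The adjusted p were 0.206 and 0.315 with an estimated correlation. Of 40 S phase genes 7 fell (median -0.21, adjusted p = 1.44e-09) and of 30 genes of MYC and ribosome biogenesis 7 fell (-0.17, 4.45e-08). Their adjusted p were 0.532 and 0.275 with an estimated correlation. Germinal-centre B cell identity genes had 7 rises and 1 fall of 30 (adjusted p = 0.0196), histone genes 1 rise of 13 (0.0301), plasma cell genes 5 rises of 21 (0.0489) and actin and adhesion genes 9 rises and 1 fall of 41 (0.025). With an estimated correlation these adjusted p were 0.532, 0.532, 0.206 and 0.275, and the actin list's median of 0.04 became -0.02 after centring on array medians. In all 1337 genes rose and 529 fell, 257 and 3 of them by at least 2-fold. The split depended on the scaling: with array medians centred 1073 rose and 1180 fell, and with renewed quantile normalization 1400 and 892. The falls depended on single arrays: 274, 296 and 302 genes fell without DMSO day 2 replicate 1, 2 and 3, and 231 and 278 without EED226 day 2 replicate 2 and 3, beside 1086, 1109, 1006, 1001 and 1076 that rose. With array weights 1943 rose and 1278 fell (3221 in all), and without EED226 day 2 replicate 2 the total was 1232.

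At day 3 IFIH1 had risen from 3.60 ± 0.30 in DMSO to 8.61 ± 0.29 with EED226 (SD, n = 3), a difference of 5.01 ± 0.17 (SE) from a dim DMSO level, and 34 of the 36 interferon genes had risen. The median of the list was 1.91 (camera adjusted p = 3.64e-55; adjusted p = 0.00088 with an estimated correlation). IFI27 rose by 4.57 ± 0.29 (SE), RSAD2 by 4.45 ± 0.24 and RTP4, an interferon-induced gene, by 4.31 ± 0.23, while RIN2 rose by 4.80 ± 0.16 and HEPACAM2, from a dim DMSO mean of 2.99, by 4.78 ± 0.16. LTA fell by 2.44 ± 0.18, TNF fell by 2.02 ± 0.15, NHSL1 fell by 2.01 ± 0.23 and the angiogenic factor VEGFA fell by 1.52 ± 0.37. VEGFA varied between the DMSO arrays with an SD of 1.48, and with only the 6 arrays compared its adjusted p was 0.136.

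Genes of proliferation and growth fell at day 3. Of 40 S phase genes 36 fell (median -0.51, adjusted p = 1.98e-22), of 48 G2 and M phase genes 28 (-0.31, 8.87e-10) and of 30 MYC and ribosome genes 21 (-0.26, 8.42e-11). The adjusted p were 0.154, 0.338 and 0.154 with an estimated correlation. Amino acid response genes (13 of 31 fell, adjusted p = 7.32e-05), cholesterol synthesis genes (9 of 22 fell and 1 rose, 0.00314), fatty acid synthesis genes (5 of 11 fell, 0.0206) and genes of the unfolded protein response (8 of 21 fell and 2 rose, 0.0308) were also called lower. Their adjusted p with an estimated correlation were 0.365, 0.365, 0.319 and 0.338. Another split of the same arrays also called 13 lists, as many as the real groups did at day 3. Upwards were MHC class I (16 of 18 rose, adjusted p = 1.83e-13), histone genes (7 of 13, 0.000246), MHC class II (8 of 16, 0.000893), germinal-centre identity (13 of 30 rose and 4 fell, 0.00271) and plasma cell genes (6 of 21 rose and 3 fell, 0.0355). Their adjusted p with an estimated correlation were 0.0769, 0.154, 0.235, 0.265 and 0.154, and the plasma cell median of 0.03 became -0.09 after centring. In all 2321 genes rose and 2215 fell, 533 and 19 of them by at least 2-fold. The more frequent direction was not settled: 1648 rose and 4460 fell after centring on array medians, where the median of all genes went from -0.02 to -0.15, 2007 and 2452 with genes above the median level, 2006 and 2130 with the mean of probe sets and 2679 and 2790 with array weights.

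**Figure D2:**
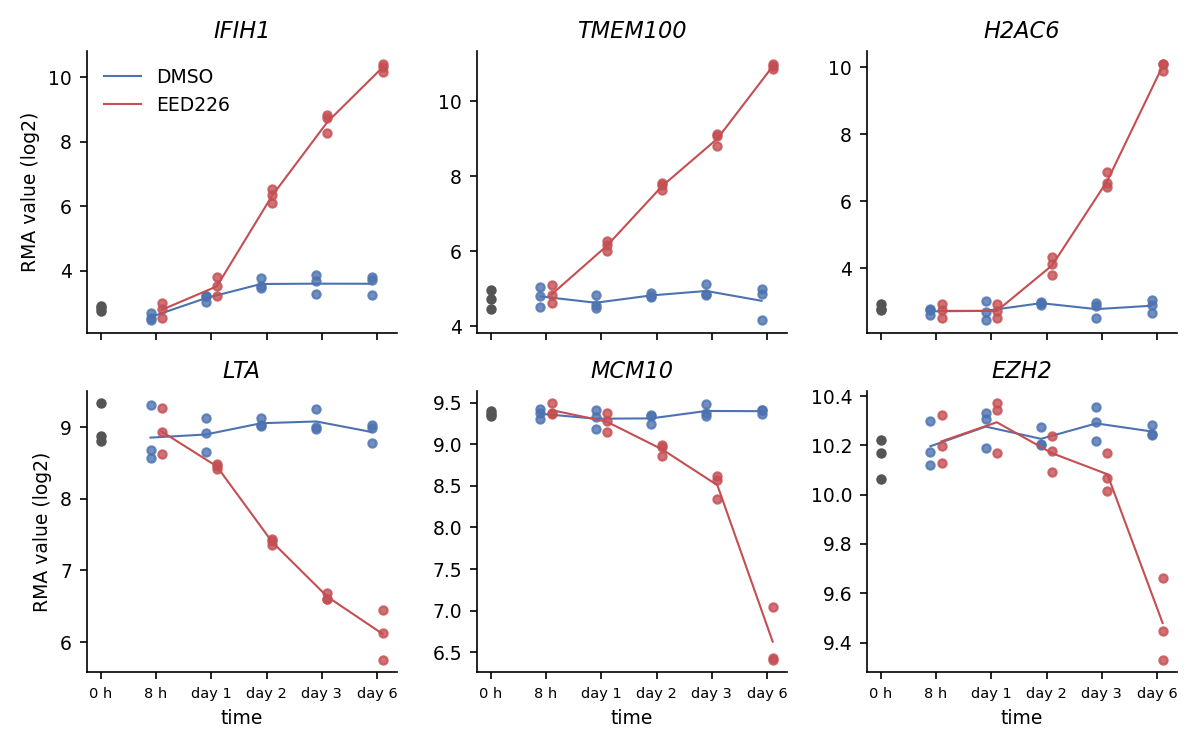
RMA values (log2, y axis) of 6 named genes on every array by time (x axis, not to scale), with DMSO in blue, EED226 in red and 0 h in grey; points are arrays and lines join group means of 3. IFIH1, TMEM100 and H2AC6 reach 10.30, 10.94 and 10.04 with EED226 at day 6, while LTA, MCM10 and EZH2 end at 6.11, 6.63 and 9.48.

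At day 6 some of the largest rises started from dim DMSO levels. H2AC6, a core histone H2A gene, went from 2.87 ± 0.19 to 10.04 ± 0.13 (SD, n = 3), a rise of 7.17 ± 0.15 log2 units (SE), measured by a probe set that can match several transcripts. IFIH1 rose by 6.70 ± 0.17, RIN2 by 6.70 ± 0.16, AIM2, a cytosolic DNA sensor, by 6.22 ± 0.21 and HEPACAM2 by 6.16 ± 0.16. The DMSO means of H2AC6, IFIH1, RIN2, AIM2 and HEPACAM2 (2.87, 3.60, 3.76, 3.68 and 3.07) lay below the lowest array median of 4.06, so the sizes and the order of these rises are uncertain. The same holds for P4HA2, TNFRSF21, NFKBIZ, BCL2A1 and H2BC21 (3.41, 2.92, 3.54, 2.55 and 2.70). From higher DMSO means, TMEM100 (4.67) rose by 6.26 ± 0.17, MPEG1, a perforin-like protein of macrophages (5.94), by 6.21 ± 0.25 and IFI27 (7.27) by 5.99 ± 0.29. LGALS13, a galectin known from placenta, fell the most, from 10.49 ± 0.46 to 6.38 ± 0.73, a difference of -4.10 ± 0.44. The checkpoint kinase CHEK1 fell by 2.92 ± 0.13, with 1 of its 3 other probe sets of opposite sign, and the replication genes MCM10 and ORC1 fell by 2.77 ± 0.11 and by 2.66 ± 0.14. LTA and TNF fell by 2.82 ± 0.18 and by 2.70 ± 0.15.

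Every measured gene of the S phase (40 of 40), G2 and M phase (48 of 48) and MYC and ribosome biogenesis (30 of 30) lists fell at day 6. Their medians were -1.75, -1.47 and -0.72, with camera adjusted p of 6.29e-30, 1.11e-27 and 1.48e-14. With an estimated correlation the adjusted p were 0.0726, 0.0805 and 0.0726. Examples were MCM6, part of the replicative helicase, at -2.11 ± 0.08, survivin (BIRC5) at -1.80 ± 0.09, cyclin B1 (CCNB1) at -1.64 ± 0.08 and fibrillarin (FBL), which modifies ribosomal RNA, at -1.35 ± 0.06. Fatty acid synthesis genes (7 of 11 fell, adjusted p = 0.000191; adjusted p = 0.0805 with an estimated correlation) included fatty acid synthase (FASN) at -2.38 ± 0.12 and SCD at -1.49 ± 0.11. Cholesterol synthesis genes (14 of 22 fell and 4 rose, adjusted p = 0.00103; adjusted p = 0.324 with an estimated correlation) included FDPS at -1.46 ± 0.09 and TMEM97 at -1.58 ± 0.08.

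Hypoxia and glycolysis genes split at day 6: 19 of 32 fell, among them enolase (ENO1) at -1.16 ± 0.06, and 6 rose, among them the prolyl hydroxylase P4HA2 at 5.94 ± 0.18, for which 1 of 2 other probe sets had the opposite sign. The list was called lower (adjusted p = 0.0191; adjusted p = 0.187 with an estimated correlation). Heat shock genes (8 of 16 fell and 3 rose, adjusted p = 0.0435; adjusted p = 0.401 with an estimated correlation) included FKBP4 at -1.16 ± 0.07 and HSP90AB1 at -0.94 ± 0.06.

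Interferon genes stayed up, with 34 of 36 higher and a median of 2.34 (camera adjusted p = 6.37e-26; adjusted p = 0.0559 with an estimated correlation), SAMD9L among them at 2.76 ± 0.09. Of 18 MHC class I genes 16 rose and 2 fell (median 1.13, adjusted p = 6.14e-08; adjusted p = 0.0843 with an estimated correlation), with the transcription factor IRF1 at 2.73 ± 0.13 and the peptide transporter TAP2, with 1 of 3 other probe sets of opposite sign, at 1.40 ± 0.09. Of 16 MHC class II genes 14 rose and 1 fell (median 0.55, adjusted p = 1.77e-06; adjusted p = 0.0726 with an estimated correlation), with CTSS, a lysosomal protease, at 1.31 ± 0.07. Histone genes had 9 rises and 2 falls of 13 (median 1.99, adjusted p = 0.000124; adjusted p = 0.0843 with an estimated correlation), with H2BC21 at 2.78 ± 0.14.

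Germinal-centre B cell identity genes had 18 rises and 5 falls of 30 at day 6 (median 0.40, adjusted p = 0.000102; adjusted p = 0.0847 with an estimated correlation). TCL1A, an AKT coactivator of B cells, rose by 5.35 ± 0.23 and the transcription repressor BACH2 by 4.57 ± 0.18. Genes reported as EZH2 targets in germinal-centre cells had 9 rises and 2 falls of 15 (adjusted p = 0.0364; adjusted p = 0.0805 with an estimated correlation), with TNFRSF21 at 5.95 ± 0.16 and TXNIP at 1.76 ± 0.11. NF-kB targets had 14 rises and 5 falls of 27 (adjusted p = 0.00577; adjusted p = 0.0726 with an estimated correlation), with NFKBIZ at 3.55 ± 0.18. Memory and activated B cell markers had 10 rises of 26 (adjusted p = 0.0093; adjusted p = 0.0843 with an estimated correlation), with BANK1, a B cell scaffold protein, at 1.40 ± 0.08; the list's median of 0.11 became -0.000348 after centring. BCL2 family genes had 6 rises and 1 fall of 16 (adjusted p = 0.0291; adjusted p = 0.0902 with an estimated correlation), with BCL2A1 at 3.32 ± 0.16 and MCL1, with 1 of 5 other probe sets of opposite sign, at 1.05 ± 0.06, both antiapoptotic, and its median of 0.19 became -0.05 with renewed quantile normalization. These lists are not separate findings, as they share members. Also on another list were 11 of the 15 EZH2 targets, 11 of 27 NF-kB targets, 13 of 26 memory markers and 4 of 16 BCL2 family genes.

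Counts adjusted over the list alone were the same at day 6 for the interferon, MHC, cell cycle and MYC lists, while 19 germinal-centre identity genes were higher and 16 cholesterol genes lower. Of the 33 lists 16 were called at day 6, and another split of the same arrays called 14. In all 4686 genes rose and 5395 fell at day 6, 1594 and 586 of them by at least 2-fold. After centring on array medians 4002 rose and 8271 fell; the median of all genes was -0.11 as deposited and -0.21 centred, so small falls lie within that shift. The more frequent direction was not settled, with 3880 higher and 3545 lower with genes above the median level and 3718 and 3304 with only the 6 arrays compared. Without DMSO day 6 replicate 3, 8829 genes passed, 4164 higher and 4665 lower.

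**Figure D3:**
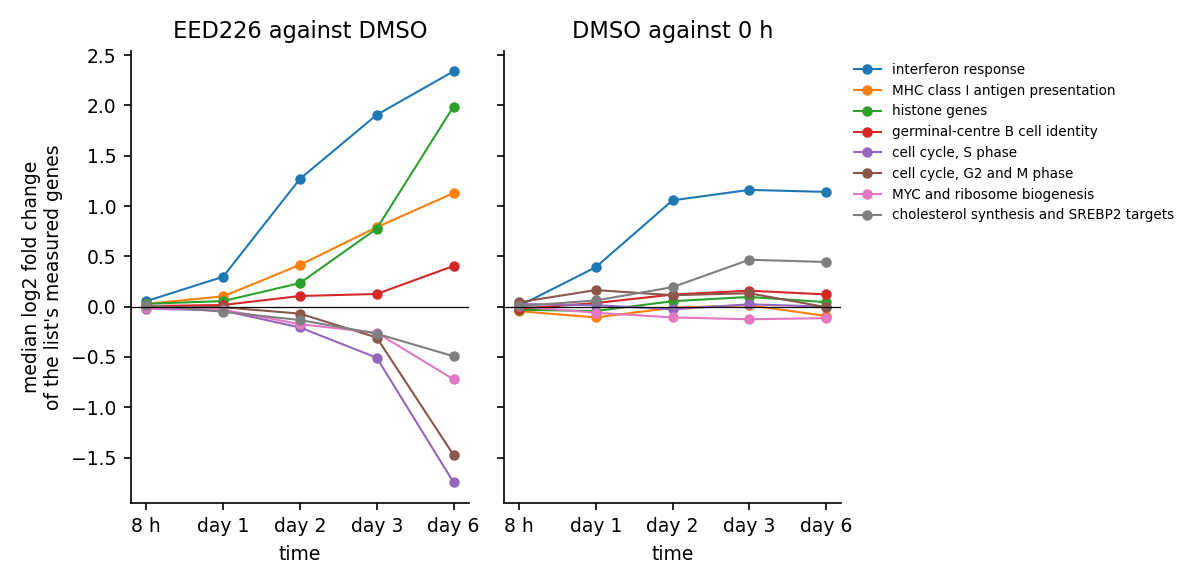
Median log2 fold change of the measured genes of 8 gene lists (y axis) by time (x axis, not to scale), for EED226 against DMSO on the left and DMSO against 0 h on the right; each point is a list's median. The interferon list reaches 2.34 with EED226 and 1.14 in DMSO at day 6, and the S phase list -1.75 with EED226.

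RNA quality measures differed most at day 6. The 3' minus 5' value of the ACTB control probe sets was 3.91 ± 0.35 with EED226 and 3.14 ± 0.24 with DMSO at day 6 (SD, n = 3), and that of GAPDH was 0.64 ± 0.11 and 0.26 ± 0.02. At 8 h and days 1, 2 and 3 the means for ACTB were 3.08, 3.11, 3.26 and 3.45 with EED226 and 3.02, 3.15, 3.18 and 3.10 with DMSO. Those for GAPDH were 0.26, 0.26, 0.33 and 0.35 with EED226 and 0.25, 0.27, 0.25 and 0.24 with DMSO, so at day 1 EED226 was not the higher group for either. Averaged over the 5 times EED226 arrays were higher by 0.244 for ACTB and 0.113 for GAPDH (2-sided permutation test within times, p = 0.0098 and 0.00059, adjusted p = 0.0196 and 0.00236 over 4 tests). At day 6 alone both exact permutation tests gave p = 0.1, the smallest that 3 against 3 arrays allow. At day 6 this difference went with the rise of interferon, MHC and histone genes and the fall of cell cycle, ribosome and lipid genes.

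**Figure D4:**
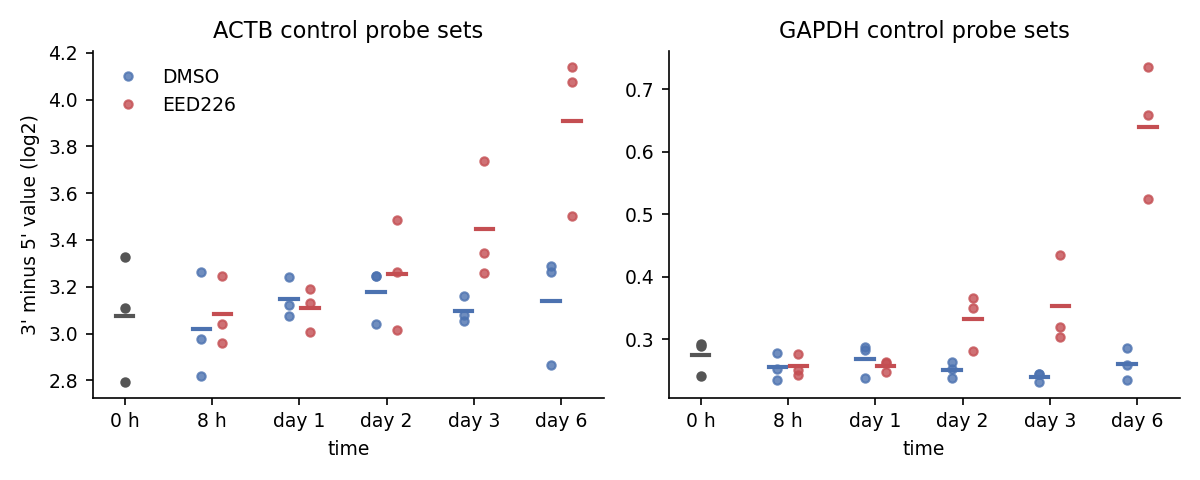
The 3' minus 5' value of the ACTB (left) and GAPDH (right) control probe sets (log2, y axis) on every array by time (x axis, not to scale), with DMSO in blue, EED226 in red and 0 h in grey; points are arrays and bars are means of 3. EED226 at day 6 has means of 3.91 and 0.64, and DMSO at day 6 has 3.14 and 0.26.

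Genes that rose early stayed up. Of 165 genes that rose at day 1, 161 also rose at day 2, 155 at day 3 and 150 at day 6, where independent lists would share 11.2, 19.4 and 39.1, and the DMSO arrays differ at each time. Their median went from 0.64 at day 1 to 1.80 at day 6. At day 6 4 of the 165 were lower. Of the 7 genes that fell at day 1, 2 fell at day 6, and independent lists would share 1.91. Across genes, which are not independent replicates, log2 changes at days 3 and 6 correlated with a Pearson r of 0.83.

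The effect of EED226 differed between days 1 and 6 for 6814 genes, 3682 more positive and 3132 more negative at day 6. Among the largest differences were H2AC6 at 7.17 ± 0.22 log2 units (SE), IFIH1 at 6.34 ± 0.24, TNFRSF21, a death receptor, at 6.03 ± 0.22, HEPACAM2 at 5.80 ± 0.23 and RIN2 at 5.76 ± 0.23, all with DMSO means below the array medians at day 6. LGALS13 was the most negative at -4.03 ± 0.63, then MCM10 at -2.74 ± 0.15, CHEK1 at -2.73 ± 0.18, and CDC45 and ORC1, which load the replication machinery, at -2.54 ± 0.16 and -2.50 ± 0.19. The more frequent direction was not settled: the split was 3179 and 4195 after centring, 3337 and 3884 with renewed quantile normalization, 3530 and 3671 with array weights and 3307 and 3327 without DMSO day 6 replicate 3.

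Between days 3 and 6 the effect differed for 4924 genes, 2802 more positive and 2122 more negative. RAG1, a recombinase of antigen receptor genes, was higher by 4.60 ± 0.24 and ZNF595 by 4.33 ± 0.32, each with 1 other probe set of opposite sign, GCA by 3.99 ± 0.15, TNFRSF21 by 3.78 ± 0.22 and TMEM71 by 3.50 ± 0.31, all with DMSO means below the array medians at day 6 (2.34, 3.00, 2.47, 2.92 and 2.57). LGALS13 differed by -3.04 ± 0.63, CHEK1 by -2.00 ± 0.18, the dynein gene DNAI1 by -1.90 ± 0.22, with 1 other probe set of opposite sign, MCM10 by -1.88 ± 0.15 and ORC1 by -1.81 ± 0.19. With renewed quantile normalization the split was 2302 and 2985.

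The DMSO cultures also changed with time. Interferon genes rose in them: 13 of 36 at day 1, 27 at day 2, 32 at day 3 and 31 at day 6 passed the test against 0 h, with medians of 0.39, 1.06, 1.16 and 1.14. Camera, run on these comparisons after seeing the data, called the list each time (adjusted p = 4.93e-38, 2.6e-95, 2.76e-82 and 9.68e-91), and called it also with adjusted p = 0.00792, 1.78e-05, 5.47e-05 and 2.6e-05 with an estimated correlation. At day 6 IFIT1 was 2.80 ± 0.14 log2 units (SE, n = 3) higher than at 0 h, IFI44L 2.61 ± 0.17, IFIT3 2.41 ± 0.14 and XAF1 1.93 ± 0.20. INSIG1, a regulator of sterol synthesis, was 1.99 ± 0.15 higher and the noncoding RNA OLMALINC 1.96 ± 0.30, from a dim 0 h mean of 3.35. Of 22 cholesterol synthesis genes 13 rose by day 6 (median 0.44, adjusted p = 3.51e-28; adjusted p = 0.0015 with an estimated correlation), and of 11 fatty acid synthesis genes 5 rose (0.34, 1.52e-12; adjusted p = 0.0015 with an estimated correlation). These values share the DMSO arrays, with opposite sign, with the EED226 comparison.

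The oxidative stress genes HMOX1 and NQO1 fell in DMSO by 1.22 ± 0.28 and by 1.19 ± 0.18 by day 6, and HES1, a Notch target, by 0.98 ± 0.18. SNX18 fell by 0.91 ± 0.15, with 1 other probe set of opposite sign, POP1 by 0.79 ± 0.19 and NRAV by 0.76 ± 0.16. At day 1 IFIT1, IFI44L and IFIT3 rose by 1.48, 1.32 and 1.23, and PSPC1, TOMM20 and CIRBP fell by 0.70, fell by 0.44 and fell by 0.39, with 2 of 4, 1 of 1 and 1 of 4 other probe sets of opposite sign. At day 2 KLF10 fell by 0.88 ± 0.14, HMOX1 fell by 1.13 ± 0.28 and NQO1 fell by 0.76 ± 0.18, and at day 3 MPEG1 fell by 1.06 ± 0.25 and HMOX1 fell by 1.19 ± 0.28.

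Several of these calls did not hold without 1 array, in fits that also have fewer arrays. PSPC1, TOMM20 and CIRBP lost theirs at day 1 without 0 h replicate 1 (adjusted p = 0.14, 0.119 and 0.201), 0 h replicate 2 (0.474, 0.288 and 0.195), and DMSO day 1 replicate 1 (0.2, 0.152 and 0.219), 2 (0.137, 0.102 and 0.113) and 3 (0.116, 0.0822 and 0.0867). Their differences in these fits were -0.54 to -0.73, -0.39 to -0.46 and -0.35 to -0.41. HMOX1 was lost without 0 h replicate 2 at days 2, 3 and 6 (0.348, 0.139 and 0.125, with differences of -0.78, -0.84 and -0.87). It was also lost at day 2 without 0 h replicate 3 (0.0725) and DMSO day 2 replicate 1, 2 and 3 (0.153, 0.0953 and 0.21), with differences of -1.04 to -1.21. The call at day 3 was lost without DMSO day 3 replicate 1 (0.0997, difference -1.01) and that at day 6 without DMSO day 6 replicate 3 (0.0746, difference -1.13). NQO1 was lost at day 2 without 0 h replicate 1 (0.176) and 3 (0.15) and DMSO day 2 replicate 1 (0.163) and 3 (0.186), with differences of -0.64 to -0.72. MPEG1 was lost without 0 h replicate 2 (0.125, difference -0.83) and DMSO day 3 replicate 1 (0.115, difference -0.86). POP1 and NRAV were lost without 0 h replicate 1 (0.206 and 0.0966, differences -0.63 and -0.67) and without DMSO day 6 replicate 3 (0.186 and 0.0697), which took their differences to -0.52 and -0.46.

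The mean of a gene's probe sets ended the calls of PSPC1, TOMM20 and CIRBP at day 1 (adjusted p = 0.819, 0.192 and 0.735, differences -0.20, -0.22 and -0.18), HMOX1 at day 2 (0.0538, -1.13), MPEG1 at day 3 (0.0517, -0.84) and SNX18 at day 6 (0.235, -0.27), and centring on array medians those of PSPC1 and CIRBP (0.0503 and 0.0602, differences -0.72 and -0.40). With only the 6 arrays compared the differences are the same and the spread comes from fewer arrays. PSPC1, TOMM20 and CIRBP then had an adjusted p of 0.477 each, HMOX1 0.254, 0.138 and 0.634 at days 2, 3 and 6, NQO1 0.21 and 0.0851 at days 2 and 6, and MPEG1 0.0969 at day 3. At day 6 the values were 0.089 for OLMALINC, 0.054 for XAF1, 0.288 for HES1, 0.685 for SNX18, 0.785 for POP1 and 0.802 for NRAV.

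The limma counts for DMSO against 0 h were 0 genes at 8 h (523 at an unadjusted p under 0.05, and 0 with every alternative run), 35 at day 1 (31 higher), 176 at day 2 (141), 598 at day 3 (418) and 341 at day 6 (164). The 523 are fewer than chance alone gives on average, which is likewise no further evidence against a change. After renewed quantile normalization 492 were higher and 383 lower at day 3, and 267 and 170 at day 6. Single arrays moved these counts. At day 1 they were 15 and 13 without 0 h replicate 1 and 2, and 14, 22 and 14 without DMSO day 1 replicate 1, 2 and 3 with at most 1 of them lower. At day 2 they were 88 and 96 without 0 h replicate 1 and 2, and 86, 90 and 87 without DMSO day 2 replicate 1, 2 and 3, with 8, 14, 8, 16 and 10 lower. At day 3 they were 357 and 358 without 0 h replicate 1 and 2, and 357 and 324 without DMSO day 3 replicate 1 and 3, with 81, 101, 93 and 75 lower.

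At day 6 the more frequent direction of change in DMSO depended on single arrays and on the setting. Against 164 higher and 177 lower with all arrays, 228 were higher and 32 lower without DMSO day 6 replicate 3, the array that stood apart from its group, 230 and 578 without replicate 2 and 157 and 332 without replicate 1. Without 0 h replicate 1 and 2 they were 99 and 28, and 126 and 109. After centring they were 155 and 119, with array weights 441 and 248, and with only the 6 arrays compared all 15 were higher. In a fit without DMSO day 6 replicate 3 the counts at days 1, 2 and 3 were 79, 285 and 953, with 14, 66 and 300 lower.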

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

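The tests of effects between times were planned; the test with the ACTB covariate was chosen after the result was seen, and the 100 splits were drawn a second time after the shares of the first draw had been seen.

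The effect of EED226 differed between days 1 and 6 for 6814 genes and between days 3 and 6 for 4924, by the limma test of the difference itself. The named genes were chosen for their changes, in part on the same day 6 arrays, so their passing this test is no separate evidence. Values below, of named genes that passed between days 1 and 6, are the effect at day 6 minus the effect at day 1, in log2 units. The sizes are uncertain where the DMSO mean lay below the lowest array median. Those with a more positive effect at day 6 were H2AC6 7.17, IFIH1 6.34, TNFRSF21 6.03, HEPACAM2 5.80, RIN2 5.76, P4HA2 5.73, IFI27 5.72, ZNF595 5.71, AIM2 5.53, MPEG1 5.31, RAG1 5.04, TCL1A 4.85, JCHAIN 4.77, TMEM100 4.74, RSAD2 4.73, ABAT 4.66, GCA 4.49, RTP4 4.35, BACH2 4.24, TMEM71 4.14, GADD45A 3.79, BCL2A1 3.65, TP53INP1 3.37, PECAM1 3.35, NFKBIZ 2.91, ZBP1 2.90, SPRED2 2.79, MAP2 2.72, ERN1 2.56, H2BC21 2.56, JUN 2.44, SAMD9L 2.40, IRF1 2.32, LYZ 2.27, MEIS1 2.22, KIAA1210 2.13, LGALS1 2.13, SLC25A43 1.71, TXNIP 1.69, MS4A7 1.65, MAEL 1.56, ECI2 1.44, BANK1 1.34, CTSS 1.28, TAP2 1.27, SERPINE2 1.25, HLA-DOA 1.16, ITGAV 1.16, MCL1 1.12, SOX9 1.07, HORMAD1 0.94, JARID2 0.92, RBL2 0.86, PRF1 0.85, EZH1 0.83, PHC1 0.81, RYBP 0.67, OCLN 0.50, DELEC1 0.45, DCN 0.44 and DSP 0.37. Those with a more negative effect were LGALS13 -4.03, MCM10 -2.74, CHEK1 -2.73, CDC45 -2.54, ORC1 -2.50, DNAI1 -2.42, LTA -2.37, FASN -2.33, TNF -2.33, MCM6 -2.04, PHF19 -1.99, NHSL1 -1.83, BIRC5 -1.82, TUBB3 -1.57, CCNB1 -1.56, TMEM97 -1.52, SCD -1.48, FDPS -1.41, FBL -1.34, MANF -1.29, WDR12 -1.25, CD247 -1.23, SHMT2 -1.22, ENO1 -1.19, FKBP4 -1.15, HSP90AB1 -0.93, EZH2 -0.80, XPOT -0.80, CDKN2A -0.78, PF4 -0.55, SUZ12 -0.41 and EED -0.25.

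For day 6 minus day 3, the largest values and those of the 2 named genes that passed there and not between days 1 and 6 were ITGA2B -0.76, VEGFA 1.89, RAG1 4.60, ZNF595 4.33, GCA 3.99, TNFRSF21 3.78, TMEM71 3.50, LGALS13 -3.04, CHEK1 -2.00, DNAI1 -1.90, MCM10 -1.88 and ORC1 -1.81.

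Among 100 splits of the arrays, the real one included, 7 gave as many genes as the 6814 between days 1 and 6 (highest other 8363) and 11 as many as the 4924 between days 3 and 6 (9294). All 6 and 10 other such splits kept the day 6 arrays in their real groups and with them the day 6 difference, so these shares do not decide whether chance can be excluded; among the 93 and 89 splits that mixed the day 6 arrays the highest counts were 3 and 2907. For the test over all times 3 of 100 splits gave as many as 8025 (highest other 8363), a share under 0.05, and the 2 others kept the day 6 groups, while the 88 that mixed them gave at most 3. The first draw, in which splits could repeat, had given 11, 6 and 2 of 100, with highest others of 7791, 7607 and 8300.

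For single times 3 against 3 arrays make 10 splits, too few for a share under 0.05. Real gene counts and the highest of the other splits were 0 and 0 at 8 h, 172 and 0 at day 1, 1866 and 0 at day 2, 4536 and 0 at day 3 and 10081 and 134 at day 6, and for gene lists 0 and 7, 5 and 3, 9 and 8, 13 and 13, and 16 and 14. For DMSO against 0 h they were 0 and 0, 35 and 0, 176 and 1, 598 and 0, and 341 and 8. All 10 splits gave as many genes or lists at 8 h, 2 as many lists at day 3, and 1, the real one, in the other cases. At days 2, 3 and 6 other splits called as many or nearly as many lists as the real groups, so a list call alone is weak evidence.

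The breadth of the response at day 6 went with a larger 3' to 5' difference of the ACTB and GAPDH control probe sets in EED226 arrays, so RNA quality may have added to it. With the ACTB difference as a covariate 9331 genes passed, against 10081, and 8240 were called in both. The median of the interferon list was 2.39 with the covariate (2.34 without), and that of the S phase list -1.79 (-1.75). The counts and both medians changed little under this covariate. Its slope came from the spread within groups (SD 0.06 to 0.35), while the ACTB means of the day 6 groups differed by 0.77. The fit therefore cannot decide whether RNA quality caused the counts or either list's shift. GAPDH, which differed too, was not used as a covariate. At day 1 neither control was higher with EED226 (ACTB 3.11 against 3.15 in DMSO, GAPDH 0.26 against 0.27). Even so 165 genes rose then, and 150 of them also rose at day 6. The median of the 165 was 0.64 at day 1 and 1.80 at day 6. These values argue against RNA quality as the cause of the rise of these genes at day 1. For the further changes at day 6 RNA quality stays open as a cause. A response to EED226, which the sample titles name, stays open throughout.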

How the results depend on the processing

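The fit without DMSO day 6 replicate 3 and the ACTB covariate were chosen after the result was seen; other settings were planned. Of 18 counts, those of genes in every comparison and of lists for EED226 against DMSO, all stayed within 1.5 times under the covariate. With the replicate block 13 of 18 did, with genes above the median level 13, renewed quantile normalization 16, centring 17, the mean of probe sets 16, trended robust eBayes 10 of 13, array weights 8 of 13, and leaving out single arrays in turn kept 119 counts within it and moved 25. Of 159 calls of named genes, all held with the block, renewed quantile normalization and array weights, 157 with centring, 157 with trended eBayes, 157 with the covariate and 116 of 139 with only the 6 arrays compared. With the mean of probe sets 151 held, 7 were lost and EED alone reversed, to 0.25. Leaving out single arrays kept 1011 and ended 63 calls of named genes. Except where the setting itself tests fewer genes or arrays, the cause was not tested. Dim genes limit the arrays, as the sizes of their changes are uncertain.

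Genes at day 1 (172) were 296 with the replicate block, 380 with array weights, 17 at 2-fold, 535 against 0 h and 284 without DMSO day 6 replicate 3. Genes at day 2 (1866) were 3221 with array weights, 260 at 2-fold and 3284 against 0 h; at 2-fold there were 552 at day 3 and 2180 at day 6. All correlations of same-numbered EED226 and DMSO arrays exceeded 0.1 only at 8 h, day 1 and day 2. No test decided whether the numbers pair the arrays at any time. Besides the count at day 1, the block moved no count of EED226 against DMSO by over 1.5 times and ended no call of a named gene. At days 3 and 6, 1 and 2 of 3 EED226 arrays correlated best with the DMSO array of their own number. For DMSO against 0 h, where arrays share only a number, the block gave 63, 271, 941 and 798 genes (main values 35, 176, 598 and 341 at days 1, 2, 3 and 6), and 2, 2, 1 and 1 of 3 arrays correlated best with their own number. The same 4 counts were 110, 336, 1019 and 853 with genes above the median level, 6, 54, 155 and 15 with only the 6 arrays, and 4, 30, 53 and 38 at 2-fold. Days 1 and 2 gave 80 and 266 with renewed quantile normalization, and day 1 gave 21 centred and day 2 115 with the mean of probe sets. Days 1, 2 and 6 gave 95, 285 and 618 with trended eBayes and 66, 344 and 689 with array weights, and days 1, 2 and 3 gave 79, 285 and 953 without DMSO day 6 replicate 3.

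Gene lists were 2 at 8 h (0) with genes above the median level and 2 at day 1 (5) with the mean of probe sets. With an estimated correlation they were 0, 1, 1 and 0 at days 1, 2, 3 and 6 (5, 9, 13 and 16), and with fry 0 at day 1 and 28 at day 6. Leaving out single arrays gave 0 to 0 genes at 8 h, 60 to 148 at day 1, 1232 to 1614 at day 2, 3705 to 4136 at day 3, 8829 to 10014 at day 6, 7399 to 8203 over all times, 6292 to 7056 between days 1 and 6 and 4307 to 5397 between days 3 and 6. Lists ranged 0 to 2, 3 to 5, 6 to 11, 11 to 14 and 14 to 16. DMSO against 0 h ranged 0 to 0, 13 to 46, 86 to 162, 324 to 525 and 127 to 808.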

Other observations

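Camera on DMSO against 0 h, DMSO at 8 h as the control and the test of early EED226 genes in DMSO were chosen after the result was seen.

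Several gene lists that did not pass as a whole at day 6 held large single changes, given in log2 units with SE (n = 3). For comparison, 4686 of all 19775 genes rose and 5395 fell. PRC1 subunits had 8 rises and 6 falls of 16 (adjusted p = 0.357), with PHC1 at 1.12 ± 0.07 and RYBP at 1.07 ± 0.08, and a median of 0.11 that became -0.00209 after centring. Developmental transcription factors known as PRC2 targets had 11 rises and 27 falls of 123 (adjusted p = 0.357), with MEIS1 at 2.96 ± 0.16 and SOX9 at 1.90 ± 0.09. Both of these rose, although falls were more frequent. Only 5 of the 123 genes were above a log2 level of 8 at 0 h. The list's median level there was 3.47, below the lowest array median of 4.06, so the sizes of its rises and falls are uncertain. Rises and falls were each a smaller share of this list than of all genes. Plasma cell genes had 9 rises and 5 falls of 21 (adjusted p = 0.357), with the joining chain gene JCHAIN at 4.78 ± 0.27 and ZBP1 at 2.78 ± 0.14; their median was -0.07 and their mean 0.42. CDK inhibitors and RB family genes had 3 rises and 3 falls of 9 (adjusted p = 0.799), with RBL2 at 0.88 ± 0.11 and CDKN2A at -0.82 ± 0.09, and a median of -0.00237, a mean of 0.09 and a median of 0.05 with renewed quantile normalization. Targets of p53 had 9 rises and 6 falls of 27 (adjusted p = 0.251), with GADD45A at 4.46 ± 0.11 and TP53INP1, whose 2 other probe sets had the opposite sign, at 3.87 ± 0.13; the median was -0.02 and the mean 0.59. Amino acid response genes had 6 rises and 14 falls of 31 (adjusted p = 0.357), with XPOT at -0.86 ± 0.08 and SHMT2 at -1.12 ± 0.11. Genes of the unfolded protein response had 8 rises and 10 falls of 21 (adjusted p = 0.402), with ERN1, 1 of its 2 other probe sets opposite in sign, at 2.95 ± 0.17 and MANF at -1.36 ± 0.09. Immediate-early and B cell receptor genes had 9 rises and 6 falls of 23 (adjusted p = 0.251), with SPRED2, both other probe sets opposite in sign, at 3.14 ± 0.17 and JUN at 2.55 ± 0.14; the median of 0.00459 became -0.10 after centring. Actin and adhesion genes had 15 rises and 11 falls of 41 (adjusted p = 0.357), with LGALS1 at 2.12 ± 0.10 and ITGAV at 1.66 ± 0.08; the median of 0.03 became -0.04 with renewed quantile normalization and -0.08 after centring. The DMSO mean of ZBP1 (3.94) lay below the lowest array median, where sizes are uncertain. In called lists, WDR12 (MYC list, 1 of 2 other probe sets of opposite sign) changed by -1.33 ± 0.06 and HLA-DOA (MHC class II, 2 of 4) by 1.42 ± 0.10.

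Markers of other cell types were measured in the same arrays, and few were above a log2 level of 8 at 0 h. The members named have the smallest p of their list. For myeloid, epithelial, and fibroblast and endothelial markers both rose, although falls were more frequent. T and NK cell markers (3 of 27 above that level) had 2 rises and 9 falls (adjusted p = 0.301), with CD247 at -1.15 ± 0.08 and PRF1, its other probe set opposite in sign and adjusted p = 0.231 with the mean of probe sets, at 0.69 ± 0.14. Myeloid markers (0 of 22 above that level) had 2 rises and 9 falls (adjusted p = 0.357), with LYZ, its other probe set opposite in sign, at 2.28 ± 0.20 and MS4A7 at 1.92 ± 0.24. Epithelial markers (0 of 18 above that level) had 2 rises and 3 falls (adjusted p = 0.518), with OCLN at 0.71 ± 0.13 and DSP at 0.45 ± 0.10. Fibroblast and endothelial markers (1 of 25 above that level) had 5 rises and 8 falls (adjusted p = 0.999), with PECAM1, 1 of 4 other probe sets opposite in sign, at 4.15 ± 0.15 and DCN, 1 of 6, at 0.58 ± 0.06; the median was -0.18, the mean 0.12 and camera pointed down. Erythroid and megakaryocyte markers (0 of 14 above that level) had 0 rises and 6 falls (adjusted p = 0.251), with ITGA2B, 1 of 3 other probe sets opposite in sign, at -0.76 ± 0.16 and PF4 at -0.41 ± 0.13. The call of PF4 was lost without DMSO day 6 replicate 3 (adjusted p = 0.0668, difference -0.33), without EED226 day 6 replicate 2 (0.102, -0.28), with the ACTB covariate (0.0968, -0.38) and with only the 6 arrays (0.0633, -0.41), and that of ITGA2B with only the 6 arrays (0.0587, -0.76). Neuronal markers (1 of 27 above that level) had 3 rises and 7 falls (adjusted p = 0.357), with MAP2 at 3.05 ± 0.19 and TUBB3 at -1.66 ± 0.10. Germline and cancer-testis genes (1 of 23 above that level) had 3 rises and 3 falls (adjusted p = 0.713), with MAEL at 1.48 ± 0.17 and HORMAD1 at 1.17 ± 0.18; their median was -0.07 and their mean 0.09. The DMSO means of LYZ, MAP2, MAEL, HORMAD1, DSP and PF4 (3.22, 3.17, 3.08, 2.59, 2.32 and 3.96) lay below the lowest array median, where sizes are uncertain.

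Camera also called other lists in the DMSO cultures against 0 h. At day 1 these were G2 and M phase genes (median 0.16, no member of 48 passed, adjusted p = 4.22e-10; adjusted p = 0.931 with an estimated correlation) and MYC and ribosome genes (median -0.06, no member of 30 passed, adjusted p = 0.000467; adjusted p = 0.931 with an estimated correlation). At day 2 they were germinal-centre identity (median 0.12, 2 of 30 rose, adjusted p = 6.5e-05; adjusted p = 0.208 with an estimated correlation), G2 and M phase (median 0.11, no member of 48 passed, adjusted p = 6.5e-05; adjusted p = 0.946 with an estimated correlation), cholesterol synthesis (median 0.19, 2 of 22 rose, adjusted p = 1.83e-09; adjusted p = 0.156 with an estimated correlation), fatty acid synthesis (median 0.24, 2 of 11 rose, adjusted p = 0.000104; adjusted p = 0.156 with an estimated correlation) and MYC and ribosome genes (median -0.11, no member of 30 passed, adjusted p = 6.5e-05; adjusted p = 0.568 with an estimated correlation). Day 3 had germinal-centre identity (median 0.16, 5 of 30 rose, adjusted p = 1.88e-07; adjusted p = 0.0498 with an estimated correlation), G2 and M phase (median 0.13, no member of 48 passed, adjusted p = 9.6e-07; adjusted p = 0.557 with an estimated correlation), cholesterol synthesis (median 0.47, 14 of 22 rose, adjusted p = 6.05e-27; adjusted p = 0.00234 with an estimated correlation), fatty acid synthesis (median 0.41, 5 of 11 rose, adjusted p = 1.42e-09; adjusted p = 0.00656 with an estimated correlation). It also had p53 targets (median 0.10, 2 of 27 rose, adjusted p = 0.0106; adjusted p = 0.264 with an estimated correlation), amino acid response (median 0.16, 3 of 31 rose, adjusted p = 0.000339; adjusted p = 0.557 with an estimated correlation), hypoxia and glycolysis (median 0.04, 3 of 32 rose, adjusted p = 0.0245; adjusted p = 0.311 with an estimated correlation) and MYC and ribosome genes (median -0.13, 1 rose and 2 fell of 30, adjusted p = 2.74e-07; adjusted p = 0.264 with an estimated correlation). Day 6 had germinal-centre identity (median 0.12, 4 of 30 rose, adjusted p = 3.44e-06; adjusted p = 0.0964 with an estimated correlation), the unfolded protein response (median -0.09, 1 of 21 fell, adjusted p = 0.0185; adjusted p = 0.411 with an estimated correlation), hypoxia and glycolysis (median 0.05, 4 of 32 rose, adjusted p = 0.00431; adjusted p = 0.168 with an estimated correlation), MYC and ribosome genes (median -0.11, 3 of 30 fell, adjusted p = 0.000168; adjusted p = 0.452 with an estimated correlation) and fibroblast and endothelial markers (median 0.11, 2 of 25 rose, adjusted p = 0.00928; adjusted p = 0.452 with an estimated correlation).

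The rise of interferon genes in the DMSO cultures is a pattern that the labels do not explain. Against DMSO at 8 h in place of 0 h, 31 of the 31 members called at day 6 were also called, with a median of 1.25 (1.27 against 0 h), which argues against the 0 h arrays as the cause. Without DMSO day 6 replicate 3, 30 of the 31 stayed called, which argues against that array. Genes that EED226 raised at day 1, without the interferon list, had a median of -0.0326 in DMSO at day 6 over 164 genes (quartiles -0.21 and 0.11, bootstrap SD 0.0171), which argues against EED226, or RNA of treated cells, in the DMSO cultures. The bootstrap treats genes as independent, and the value was not computed without DMSO day 6 replicate 3. Genes called higher by at least 2-fold at day 6 differed in that array by -0.32 from the other arrays of its group, so the limit of this test is not known exactly. Time in culture, medium and DMSO itself could each lie behind the rise of interferon genes in DMSO and were not tested.

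More genes rose than fell with EED226 at days 1 and 2, and a candidate explanation is that dim genes can only rise on these arrays. Among called genes with a DMSO mean above 8, 94.4% rose at day 1 (17 of 18, exact Clopper-Pearson 95% interval 72.7 to 99.9). This argues against it for these 18 of the 172 called genes only. For the dimmer called genes of day 1 the explanation stays open. The intervals treat genes as independent of each other, which they are not. At day 2 the share was 52.3% (395 of 755, interval 48.7 to 55.9), so the excess of rises at day 2 lay in dimmer genes and the explanation stays open. Loss of repression at genes that were off, which an inhibitor of PRC2 would give, also predicts rises of dim genes and was not told from it. The split at day 2 depended on centring as well, with 1073 rises and 1180 falls after it.

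DMSO day 6 replicate 3 had r of 0.987 and 0.986 with the other arrays of its group. Its median difference from them was 0.09 for genes under a log2 level of 4, -0.04 from 4 to 6, -0.42 from 6 to 8, -0.18 from 8 to 10 and -0.05 above 10. Genes called higher by at least 2-fold without it (1377, median effect 1.53) differed in it by -0.32, and genes called lower (702, -1.31) by -0.17.

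As a hypothesis, genes that change with EED226 may lie next to each other on chromosomes. Among 17192 neighbouring pairs of measured genes, leaving out pairs whose symbols share their first 3 letters, a one-sided permutation test of the calls was run; both genes were higher at day 1 in 4 pairs (mean of 10000 shuffles 1.2, p = 0.03, 165 genes) and at day 2 in 153 (79.0, p = 0.0001, 1337 genes). The 4 pairs of day 1 still lay within the middle 95% of the shuffles, so day 1 stays open. In the same permutation test both were at least 2-fold higher at day 6 in 177 pairs (112.1, p = 0.0001, 1594 genes) and at least 2-fold lower in 31 (15.1, p = 0.0003, 585 genes); 0.0001 is the smallest p that these shuffles can give. The shuffles do not keep the level of a gene, so a shared baseline of neighbours stays open.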
